A study of Homo sapiens with 24 samples.

How the data were processed

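RNA from saliva was measured on an Affymetrix expression array in 24 human samples, 12 labelled pancreatic cancer and 12 labelled healthy control. The labels describe total RNA with a biotin label and 1 channel per array. They name neither donors, batches nor the amplification used, so p-values measure the spread between these samples.

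The deposited values are probe set intensities on a linear scale, made by the authors with Affymetrix Expression Console and PLIER, a method that summarises the probes of a probe set, per the submitters' processing notes. Versions, background correction and normalization options were not given in the sources used here. The 24 columns do not share 1 distribution, so the scale between arrays and any centring of it remain unknown. The values were judged linear because they include exact zeros and reach from 4405 to 68604 at their maximum. Median intensities of the 12 cancer arrays, replicates 1 to 12, were 1.92, 1.97, 1.72, 2.01, 1.86, 1.88, 1.70, 1.84, 1.65, 1.83, 1.98 and 1.87. Median intensities of the 12 control arrays, replicates 1 to 12, were 1.96, 1.92, 1.97, 1.72, 1.60, 1.97, 1.64, 1.54, 1.14, 1.77, 1.57 and 1.80. Exact zeros made up 14.8% to 28.8% of an array's values, and 5.69% to 7.31% of values exceeded 100. No detection calls were used here, so most probe sets cannot be told from background, and the number of arrays limits the precision. Spearman correlations between pairs of arrays lay between 0.245 and 0.585, so no array was a copy of another.

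Of 54675 probe sets, 62 array controls and 96 probe sets of XIST or Y-linked genes stayed out of every test. Among the 54517 tested probe sets, GEO's platform annotation gave 1 gene symbol to 41028, several to 1768 and none to 11721. Probe sets with several symbols or none are not named, and coordinates are not used here. Symbols were brought up to date by gene number through RefSeq names of assembly GRCh38.p14, where 54 had no match and 0 changed. A gene was represented by its probe set of highest mean log2 value over all 24 arrays among those with 1 symbol, which gave 19738 genes. Other probe sets of the same gene disagreed in several cases. They are given for the named genes called between the groups, the candidates and a few others, and not for the remaining genes.

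Intensities were tested as log2(intensity + 16). A fold change on this scale understates the change of dim probe sets. The groups were compared with limma 3.58.1 (lmFit and eBayes, no trend, not robust) in R 4.3.3, 2-sided, with group as the only term and Benjamini-Hochberg adjustment over all tested probe sets at 0.05. A probe set past that threshold is called. The 25 gene lists were fixed before the data were examined, with 642 of 729 entries measured. They comprised published candidates, salivary gland secretory, oral squamous epithelium, neutrophil, monocyte macrophage, T and NK lymphocyte, B and plasma cell, erythrocyte, ribosomal protein, translation factor, oxidative phosphorylation, interferon response, NF-kB and inflammatory cytokine, immediate early and stress, hypoxia and glycolysis, cell cycle, pancreatic ductal carcinoma, pancreatic exocrine and islet, RAS and MAPK pathway, saliva oral cancer panel, housekeeping, testis restricted, olfactory and taste receptor, neuronal, and skeletal and cardiac muscle genes. Lists were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry for a shift in 1 direction, with adjustment over the lists. Of the 12 published candidates, 11 were measured and the other is not reported here. As a check planned for RNA integrity, which the low 5' signal did not allow, the 3' minus 5' log2 signal of the ACTB and GAPDH controls was compared by a 2-sided permutation test with 100000 resamples, or by exact enumeration where fewer splits exist.

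The genes named were chosen by a rule fixed before the data were examined. It takes the 12 higher and 12 lower genes of smallest p past the threshold, limited to an absolute log2 difference of at least 1 where a direction has 12 such genes. Where fewer than 6 of a direction pass, it takes the 6 of smallest raw p, said to miss the threshold. It also takes every published candidate by its representative probe set and up to 4 members of smallest p in each list. Genes named from the comparisons of array sets, and non-representative probe sets of the candidates, were chosen after their values were seen.

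Arrays fell into separate sets by a hybridization control, described with the results. The array set as a block and each set alone were added as alternatives after the data were seen, and the 3' minus 5' signal was also compared between the sets then. The alternatives fixed before the data were examined were offsets of 1 and 64, quantile normalization, median centring, leaving out dim probe sets, a variance trend with robust fitting, an exact Wilcoxon test (Python 3.11.15 with numba 0.67.0), array weights, leaving out 1 array of low correlation with the rest (by more than 3 scaled MADs), the 3' minus 5' signal as a covariate, the replicate number as a block, leaving out each array in turn, representative probe sets only, and the mean of a gene's probe sets. The procedure was tested on simulated data for the comparison of cancer with control over 54517 probe sets, with 50 probe sets changed at each size. It recovered 36% at a log2 difference of 1, 74% at 2, 94% at 3 and 100% at 4, with 13 false calls, and called 1 list, the planted one. The changed probe sets were drawn from brighter named ones, above the mean values of the named probe sets called below. Noise was drawn independently for each probe set. The rates therefore do not hold for dim probe sets, nor the list result for genes that move together. Other splits of the samples were drawn 100 at a time. Figures were drawn with matplotlib 3.10.9.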

Results

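Saliva RNA from 12 pancreatic cancer samples and 12 healthy control samples was compared on an expression array with 54675 probe sets. The question, as the series title puts it, is whether salivary transcripts mark pancreatic cancer. Signal was low on every array, with median intensities between 1.14 and 2.01. Values below are log2(intensity + 16) unless an intensity is named, and differences are cancer minus control.

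Between the groups, 1 probe set each of 3 named genes fell in cancer saliva, and in each gene another, brighter probe set did not. CD7, a surface antigen of T and NK cells, had a mean of 4.14 ± 0.15 (SD, n = 12) in cancer and 5.44 ± 0.60 (SD, n = 12) in control samples, a log2 difference of -1.30 (SE 0.17, limma adjusted p = 0.00629). Its median intensity was low in both groups, 30.8 in controls and 1 in cancer. PNPLA8, a calcium-independent phospholipase, fell by 1.93 on the log2 scale (SE 0.29, adjusted p = 0.0136), from a median intensity of 77.4 in controls to 4.9 in cancer. CDKL3, a cyclin-dependent kinase-like protein, fell by 0.91 on the log2 scale at 1 of its probe sets (SE 0.14, adjusted p = 0.0136), from a median intensity of 17.2 to 0. Each of these was below the control median in 12 of 12 cancer samples. The representative, brightest probe set had 0.83 (SE 0.38, unadjusted p = 0.0402) for CD7, the opposite sign, -0.01 (SE 0.42) for PNPLA8 and -0.15 (SE 0.35) for CDKL3. Whether the probe sets of a gene measure the same transcripts was not tested. With representative probe sets only, limma called 0. The remaining call was 1 probe set higher in cancer that is unnamed here, so that limma called 4 of 54517 probe sets, 1 higher and 3 lower. At an unadjusted p under 0.05 there were 2578 probe sets, against 2726 expected by chance alone. An exact Wilcoxon test called 2, CD7 and S100P.

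**Figure D1:**
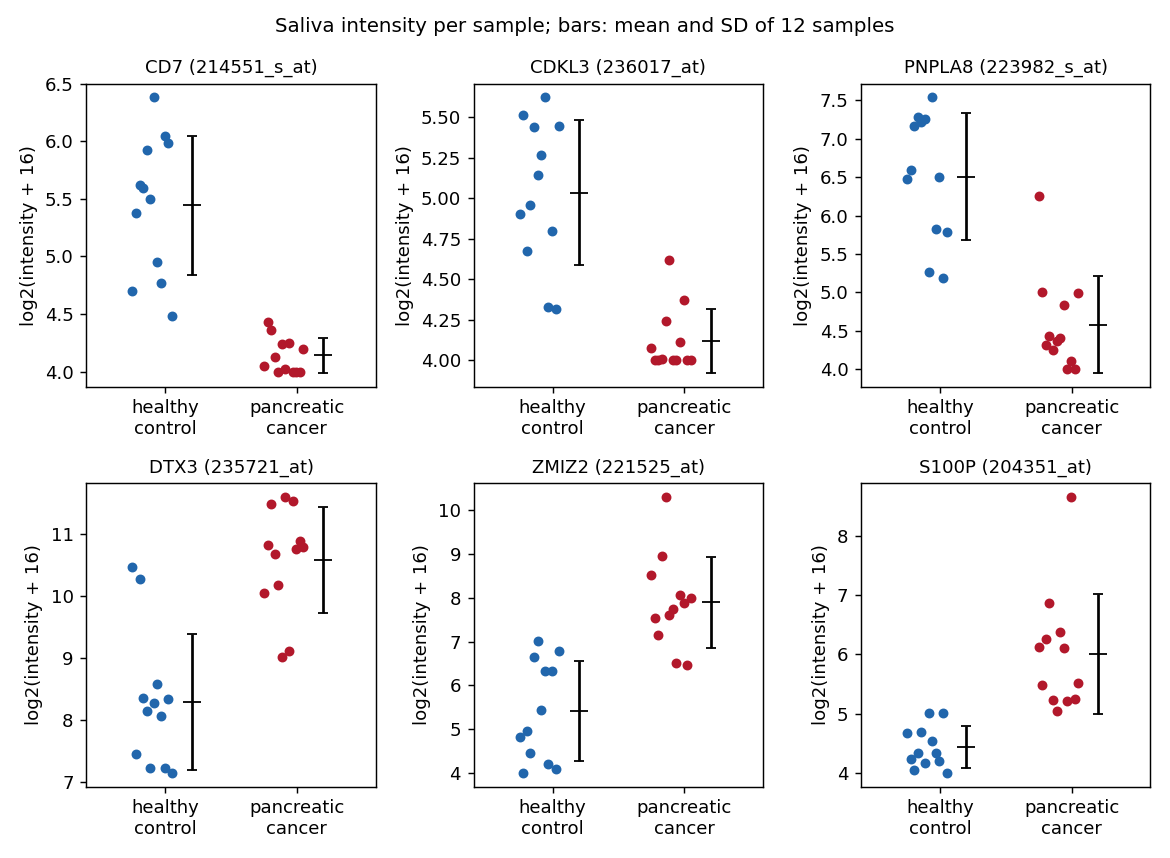
Each point is 1 saliva sample, on a vertical axis of log2(intensity + 16), by group (blue, healthy control; red, pancreatic cancer), with the mean and SD of 12 samples beside the points. CD7, CDKL3 and PNPLA8 passed the adjusted threshold with log2 differences of -1.30, -0.91 and -1.93; DTX3, ZMIZ2 and S100P, at 2.28, 2.47 and 1.57, missed it.

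No named gene passed the threshold as higher in cancer. The 6 of smallest raw p all missed it, and each lay above the control median in 12 of 12 cancer samples. DTX3, a Deltex-family ubiquitin ligase, differed by 2.28 (SE 0.39, adjusted p = 0.0518), with median intensities of 1740 in cancer and 280.6 in controls. ZMIZ2, a PIAS-like transcriptional coactivator, differed by 2.47 (SE 0.43, adjusted p = 0.0654). The ferritin heavy chain pseudogene FTH1P5 differed by 3.15 (SE 0.57, adjusted p = 0.0807) at a probe set whose probes can also match related ferritin transcripts. The kinase LRRK1 differed by 1.99 (adjusted p = 0.0807), the TGF-beta co-receptor endoglin, ENG, by 1.36 (adjusted p = 0.107), and the secreted glutathione peroxidase GPX3 by 2.06 (adjusted p = 0.107). Among lower genes that missed the threshold, TPBGL differed by -1.20, TK2, the mitochondrial thymidine kinase, by -1.26 at a dim probe set, and SEC23IP by -0.23, with adjusted p from 0.496 to 0.607. Of 11 alternatives fixed before the data were examined, 5 called DTX3 (lowest adjusted p = 0.0149), 4 FTH1P5, 3 ZMIZ2, 2 each LRRK1 and ENG, and 1 GPX3, and without 1 array DTX3 and ZMIZ2 were each called in 4 of 24 fits. With an offset of 64 in place of 16 limma called 0 probe sets, and with an offset of 1 it called 9. A variance trend with robust fitting ended the call of CDKL3 (adjusted p = 0.104), and the Wilcoxon test ended those of CDKL3 and PNPLA8 (adjusted p = 0.0968 each). With the replicate number as a block limma called 0 probe sets, though samples share only that number across groups.

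The published candidate genes were chosen on these samples, so their counts are not independent evidence. By representative probe set, 0 of 11 passed over all probe sets with limma, 4 had an unadjusted p under 0.05, and 4 passed adjusted over the list alone. MBD3L2, a relative of methyl-CpG-binding proteins, had a log2 difference of 1.77 (SE 0.52), from a median intensity of 15.4 in controls to 149.9 in cancer. STIM2, an endoplasmic reticulum calcium sensor, had 1.27 (SE 0.33), and DMD, the dystrophin gene, 0.79 (SE 0.22). DPM1, a subunit of dolichol-phosphate mannose synthase, had -0.67 (SE 0.18). ACRV1, an acrosomal protein of sperm, had 0.83 (SE 0.48), and TPT1, the translationally controlled tumour protein, had -0.75 (SE 1.10). TK2 had 0.33 (SE 0.49), CABLES1 -0.16 (SE 0.12), CDKL3 -0.15 (SE 0.35), DMXL2 -0.15 (SE 0.24) and NOP53 0.01 (SE 0.04).

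Probe sets of a candidate gene often disagreed. Of 34 candidate probe sets, 1 passed over all probe sets (CDKL3) and 10 had an unadjusted p under 0.05, in 10 genes. For 6 of these genes that probe set was not the representative one. CABLES1 had 1.39 (SE 0.27) at such a probe set against -0.16 at its brighter representative, and DMXL2 had 1.18 (SE 0.35) against -0.15. ACRV1 had 1.37 (SE 0.34) against 0.83, and TPT1 had -2.05 (SE 0.84) against -0.75. TK2 had opposite signs, -1.26 at the dim probe set and 0.33 at the representative one. These probe sets were picked after their values were seen. With the mean of a gene's probe sets in place of the representative, 8 of 11 candidates passed adjusted over the list alone.

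Over all 24 arrays camera called 0 of 25 lists between the groups (lowest adjusted p = 0.677), and none passed with an estimated correlation (lowest adjusted p = 0.727) or with fry (lowest adjusted p = 0.766). With array weights the ribosomal protein list passed as higher in cancer (median 0.18, adjusted p = 0.00846), but not with an estimated correlation (p = 0.196, adjusted p = 0.52). Among the 33 pancreatic ductal carcinoma genes, 2 had an unadjusted p under 0.05 on the higher side and 1 on the lower, with a median log2 difference of 0.05. S100P, a calcium-binding protein abundant in pancreatic ductal carcinoma, differed by 1.57 (SE 0.30, limma adjusted p = 0.109), with median intensities of 41.0 in cancer and 4.1 in controls, and was above the control median in 12 of 12 cancer samples. It passed with the Wilcoxon test (adjusted p = 0.0202) and with an offset of 1, and its adjusted p ranged from 0.00832 to 0.95 over the alternatives fixed before the data were examined. KRT19, a ductal keratin, had 0.16, osteopontin, SPP1, had -0.62, and mesothelin, MSLN, had -0.09. The 19 pancreatic exocrine and islet genes had a median of 0.01 and 0 at an unadjusted p under 0.05. Of these, INS had 0.50 (SE 0.25), TTR -0.82, PNLIP -0.12 and CPA1 0.15.

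Lists of gland and mouth lining genes passed no test between the groups. The 26 salivary gland secretory genes had a median of 0.04 and 0 at an unadjusted p under 0.05, with 0.70 for ZG16B, 0.68 for carbonic anhydrase CA6, 0.15 for PRB4 and 0.09 for PRB3. The 33 oral squamous epithelium genes had a median of 0.09. Of these 2 were nominally higher (cornulin, CRNN, at 0.40 and stratifin, SFN, at 0.26) and 1 lower (periplakin, PPL, at -1.17), and KRT10 had -0.44.

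Blood cell lists likewise passed no test. The 32 neutrophil genes had a median of -0.08 and 0 nominal changes, with -1.89 (SE 1.03) for serglycin, SRGN, 0.27 for FCGR2A, -0.12 for FFAR2 and -0.11 for ALPL. The 15 monocyte macrophage genes had a median of -0.01, and AIF1 had 0.70, TYROBP -0.83, FCN1 0.07 and MRC1 -0.05. Of the 19 T and NK lymphocyte genes, NKG7 was nominally higher (0.12) and granulysin, GNLY, nominally lower (-1.14), around a median of -0.01, and CCR7 had 0.09 and CD3D -0.13. The 15 B and plasma cell genes had a median of -0.02, and CD79A had -0.63, CD22 -0.10, CD79B 0.07 and POU2AF1 0.24. The 8 erythrocyte genes had a median of 0.00, and HBB had -0.11, ALAS2 0.09, HBM -0.05 and CA1 -0.35.

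Lists of cell growth and metabolism gave small medians. The 51 ribosomal protein genes had a median of 0.07 with 1 nominal change (RPL35, 0.12), and RPL39 had 1.11 (SE 0.60), RPS14 0.69 and RPL7 0.33. Of 16 translation factor genes, EIF3E (0.29) and BTF3 (0.63) were nominally higher, around a median of 0.02, and EIF3K had 0.75 and EEF2 0.18. The 33 oxidative phosphorylation genes had a median of 0.04 and 0 nominal changes, with 0.13 for ATP5MC3, 0.16 for NDUFA6, 0.08 for NDUFA13 and -0.33 for ATP5MG. Of the 30 cell cycle genes, TPX2 (0.29) and MCM7 (0.79) were nominally higher and CCNB1 (-0.21) nominally lower, around a median of -0.01, and PCNA had -0.37. Only TPX2 passed adjusted over the list alone among them, at a median intensity of 4.6 in cancer. The 22 hypoxia and glycolysis genes had a median of 0.07 with HK2 (0.18) and PGK1 (0.30) nominally higher, and NDRG1 had -0.17 and GPI -0.11. The 31 RAS and MAPK pathway genes had a median of 0.02 with RALA nominally higher (0.48), and DUSP4 had 0.60, DUSP6 -0.15 and MAP2K2 -0.10. The 17 housekeeping genes had a median of -0.05, with GUSB nominally lower (-0.16) and PGK1 nominally higher, and UBB had -0.74 and TUBA1B -0.51.

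Inflammatory and stress lists were similar. The 30 interferon response genes had a median of 0.01 and 0 nominal changes, with 0.69 for OAS1, 0.13 for MX1, 0.09 for OASL and -0.64 for ISG20. Of 24 NF-kB and inflammatory cytokine genes, CXCL3 was nominally higher (0.16), around a median of 0.06, and CXCL8, the neutrophil attractant interleukin 8, had -1.49 (SE 0.93), NFKBIA 0.41 and IL6 0.10. Of 22 immediate early and stress genes, MYC was nominally higher (0.31) and NR4A1 nominally lower (-1.20), around a median of -0.03, and EGR1 had -0.87 and DUSP1 0.61. In the 7-gene saliva oral cancer panel, S100P was nominally higher and SAT1, the spermidine acetyltransferase, nominally lower (-2.32, SE 1.04), around a median of 0.11, and IL1B had 0.75. Another IL1B probe set had -0.16 (SE 0.62).

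Lists chosen beforehand for genes not expected in saliva also gave small medians. These were 0.01 for 39 testis restricted genes (MBD3L2 nominally higher; ODF2 0.54, SPAG6 0.58 and DKKL1 0.68), -0.02 for 48 olfactory and taste receptor genes (OR7A17 0.13, OR1C1 -0.16 and TAS2R8 -0.14 nominal; TAS2R3 -0.08), -0.02 for 28 neuronal genes (DLG4 0.11 nominal; GRIN2A 0.12, STMN2 -0.96 and SYT1 -0.10) and 0.02 for 33 skeletal and cardiac muscle genes (DMD nominal; MYOZ1 0.16, MYL11 0.11 and CKM 0.55). None of these lists passed the threshold.

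**Figure D2:**
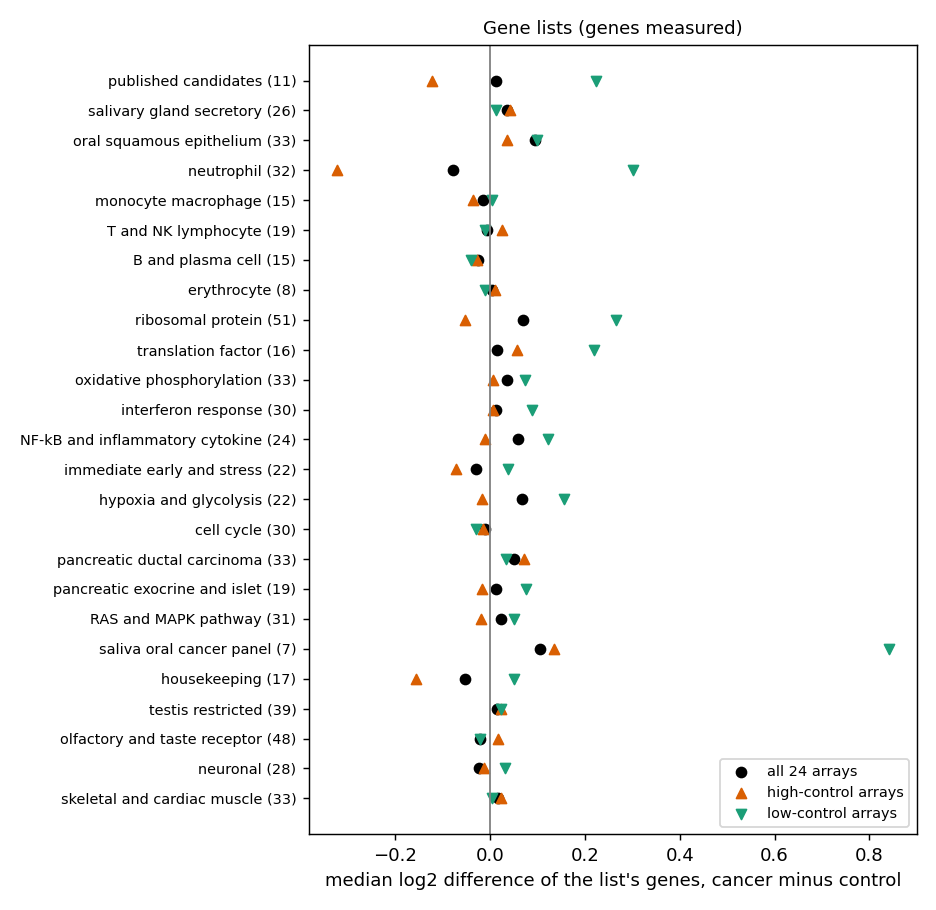
Each row is 1 of 25 gene lists, with the number of its genes measured in parentheses, and the horizontal axis is the median log2 difference of its genes, cancer minus control. Black circles are all 24 arrays, orange and green triangles the 13 high-control and the 11 low-control arrays; the neutrophil list lies at -0.08, -0.32 and 0.30.

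The arrays themselves formed separate sets that did not follow the groups. BioB, a bacterial transcript added before hybridization, had an intensity of at least 1569 on 13 arrays, called high-control here, and of at most 735.1 on the other 11, called low-control. The high-control arrays held 7 cancer and 6 control samples and the low-control arrays 5 and 6 (Fisher's exact p = 1). These sets were defined after the data were seen and are not groups of the study. The first principal component, with 24.8% of the variance, placed all 13 high-control arrays apart from the low-control ones.

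**Figure D3:**
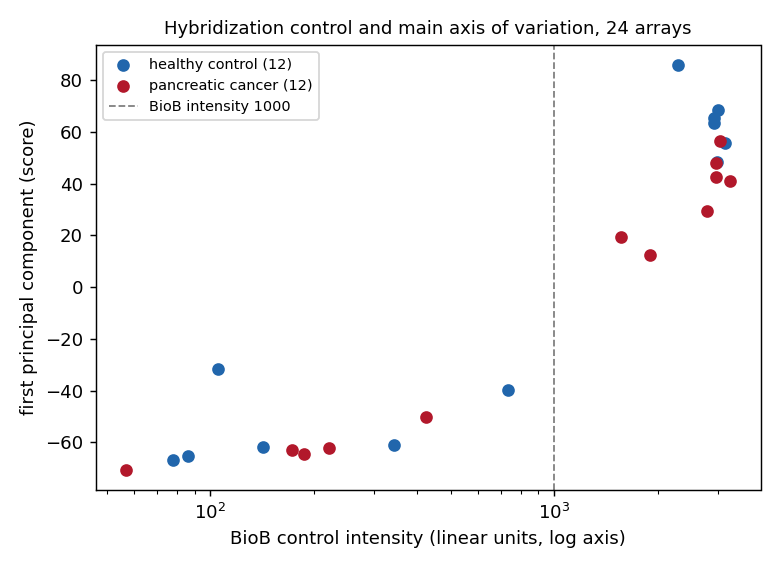
Each point is 1 array, with the BioB control intensity on a log horizontal axis and the score on the first principal component (24.8% of variance) on the vertical axis, by group (blue, 12 healthy control; red, 12 pancreatic cancer). The 13 arrays right of the dashed line at an intensity of 1000 all score above the 11 to its left, and both groups lie on both sides.

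Some transcripts abundant in saliva were brighter on the high-control arrays, while more probe sets went the other way. S100A8, a calprotectin subunit of neutrophils, had a median intensity of 2364 on high-control and 36.1 on low-control arrays, a log2 difference of 4.16 (limma adjusted p = 0.000458). A dimmer S100A8 probe set had 1.52 and missed the threshold (adjusted p = 0.269). SPRR3, a cornified envelope protein of oral epithelium, differed by 3.53 (adjusted p = 0.000845) and S100A9 by 3.88 (adjusted p = 0.000914). Of the 51 ribosomal protein genes, 16 were called higher and 3 lower on high-control arrays (camera adjusted p = 5.5e-05; adjusted p = 0.615 with an estimated correlation). The salivary gland secretory list was also higher there (median 0.19, camera adjusted p = 0.0312; adjusted p = 0.213 with an estimated correlation), including PIGR, the polymeric immunoglobulin receptor, at 1.78. The basal keratin KRT14 went the other way, at -2.30 (limma adjusted p = 7.27e-09), as did IL1B, at -1.31 and at -0.49 by another probe set, which both missed the threshold. The oral squamous epithelium list (median -0.01, camera adjusted p = 0.914) and the neutrophil list (median 0.18, camera adjusted p = 0.226) did not pass. In all, 4051 of 54517 probe sets differed between the array sets, 1214 higher and 2837 lower on high-control arrays.

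With the array set as a block, limma called 6 probe sets between cancer and control, 3 higher and 3 lower, including all 4 from the fit without it. The added named genes were UTF1, a chromatin factor of pluripotent cells, at 2.30 (adjusted p = 0.0176), and ZMIZ2 at 2.52 (adjusted p = 0.0405). CD7, PNPLA8 and CDKL3 had -1.32, -1.90 and -0.91. Within each set these 3 probe sets kept their sign but missed the threshold: CD7 had -1.45 on high-control and -1.17 on low-control arrays, PNPLA8 -1.96 and -1.84, and CDKL3 -0.83 and -1.01. With the block 0 of 25 lists passed (lowest camera adjusted p = 0.736).

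On the high-control arrays, 7 cancer against 6 control samples, limma called 4 probe sets. UTF1 was higher by 3.07 (SE 0.15, adjusted p = 1.93e-06) and IFI27L1, an interferon-inducible family member, by 2.84 (SE 0.29, adjusted p = 0.00499). TPT1, at the probe set that was not its representative, fell by 4.74 on the log2 scale (SE 0.45, adjusted p = 0.00391), from a median intensity of 1233 in controls to 12.9 in cancer. Its representative had -2.93 there, other TPT1 probe sets -2.55 and -1.84, and a dim one -0.16, all missing the threshold (adjusted p = 0.854 each). SAT1 fell by 5.61 on the log2 scale (SE 0.65, adjusted p = 0.0151), from 2243 to 13.1. Other SAT1 probe sets missed the threshold, at -4.12 (adjusted p = 0.659) and, near background, -0.09. The neutrophil list was lower in cancer on these arrays (median -0.32, camera adjusted p = 0.00029), with 22 of 32 genes below 0 and 4 passing adjusted over the list alone. With an estimated correlation it did not pass (p = 0.0477, adjusted p = 0.398). SRGN had -4.25, CXCL8 -3.52, S100A8 -1.66 and the chemokine receptor CXCR2 -0.51, and without pancreatic cancer replicate 6 S100A8 had -0.73.

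On the low-control arrays, 5 cancer against 6 control samples, limma called 2 probe sets, both higher and unnamed here. Cancer arrays were higher for 5 lists there by camera: neutrophil (median 0.30, adjusted p = 0.012), ribosomal protein (0.27, adjusted p = 7.53e-05), translation factor (0.22, adjusted p = 0.0444), hypoxia and glycolysis (0.16, adjusted p = 0.024) and saliva oral cancer panel (0.84, adjusted p = 0.00304). With an estimated correlation 0 passed (lowest adjusted p = 0.575). Without pancreatic cancer replicate 1, 0 of the 5 lists passed, and the neutrophil median became 0.00 (adjusted p = 0.989). S100A8 had 2.21 on these arrays, and SAT1 1.0, the same TPT1 probe set 0.67 and CXCL8 0.40. Median intensities there, control then cancer, were 11.6 and 23.4 for SAT1, 11.7 and 18.1 for TPT1 and 3.5 and 4.6 for CXCL8. These lie near background, so the fall seen on high-control arrays could hardly show for these genes. IFI27L1 had -0.86, against its higher value on high-control arrays, and UTF1 had 1.38. Without pancreatic cancer replicate 1 SAT1 had 0.36 and CXCL8 -0.18, and without pancreatic cancer replicate 4 that TPT1 probe set had 0.35.

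**Figure D4:**
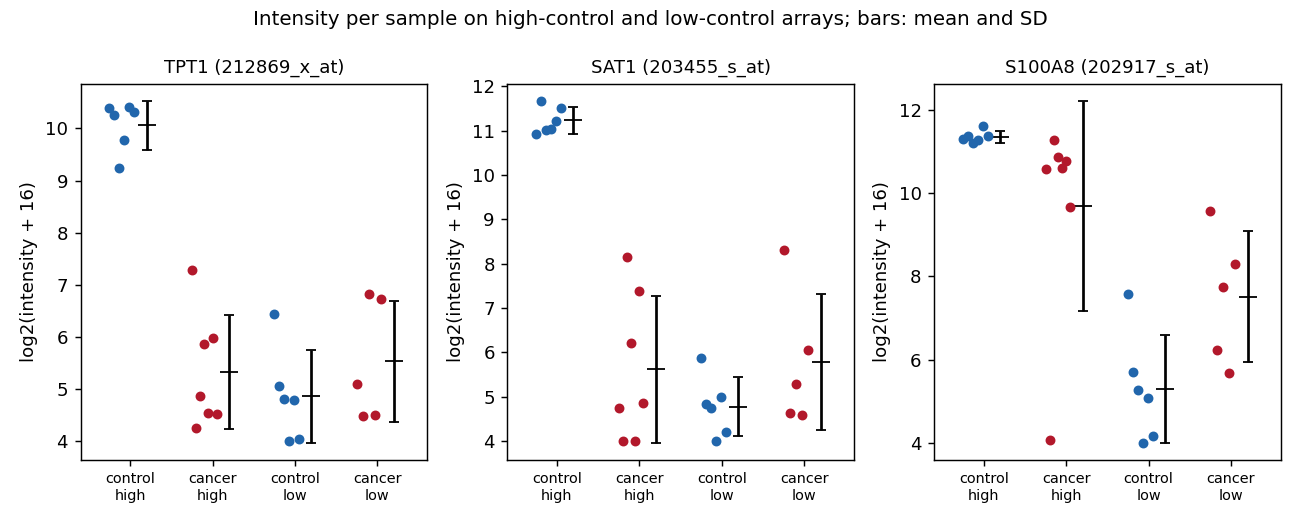
Each point is 1 sample, on a vertical axis of log2(intensity + 16), by group and array set (control blue, cancer red; high-control and low-control arrays), with the mean and SD of 6, 7, 6 and 5 samples from left to right. At the called probe sets shown, TPT1 and SAT1 are bright on the 6 high-control arrays of control samples, with log2 differences of -4.74 and -5.61 for the 7 of cancer samples.

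The 3' minus 5' signal of the ACTB and GAPDH controls averaged 0.60 ± 0.73 (SD, n = 12) in cancer and 0.56 ± 1.03 (SD, n = 12) in control samples (difference 0.03, permutation p = 0.924). Within high-control arrays the difference was -0.45 (exact permutation p = 0.386), and within low-control arrays 0.42 (exact permutation p = 0.0217). The signal was higher on high-control than on low-control arrays, 1.06 ± 0.91 (SD, n = 13) against 0.02 ± 0.34 (SD, n = 11; difference 1.04, permutation p = 0.00206). The 5' controls averaged 4.17 and 4.21 on these sets and the 3' controls 5.23 and 4.23, where an intensity of 0 gives 4. The 5' end thus lay near background in both sets, and the 3' end did so on low-control arrays as well. The difference between the sets follows the level of the 3' end and does not measure RNA integrity. The group difference of 0.42 within low-control arrays rests on values near background.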

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

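The array sets were defined after the data were seen, so every test between or within them, and the tests of TPT1 probe sets, were chosen after seeing results. A different group effect on high-control and low-control arrays brought forward each result here, by a limma or camera test of the difference itself. Values are the cancer minus control effect on high-control arrays minus that on low-control arrays. SAT1 had -6.61 on the log2 scale and TPT1, at the probe set called on high-control arrays, -5.41, and UGGT1, a glycoprotein folding sensor of the endoplasmic reticulum, had 2.61 (limma adjusted p = 0.0102 for each). On low-control arrays the control samples had median intensities of 11.6 for SAT1 and 11.7 for that TPT1 probe set, near background. A fall in cancer could hardly show there, so for these 2 the test says little about a different group effect. In all 4 of 54517 probe sets passed, 1 of them unnamed here. Other splits of the groups gave a count as large in 3 of 100 cases, the real one included (highest other 6), so the count of 4 was larger than chance gives in most splits.

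By camera 5 lists passed: neutrophil (median -0.68), saliva oral cancer panel (-0.68), ribosomal protein (-0.35), immediate early and stress (-0.34) and hypoxia and glycolysis (-0.15). With an estimated correlation 0 of 25 passed (lowest adjusted p = 0.166). Without pancreatic cancer replicate 1, 1 of these 5 passed, neutrophil (median -0.37, adjusted p = 0.00456), and the others had -0.04 (saliva oral cancer panel), -0.22 (ribosomal protein), -0.24 (immediate early and stress) and -0.12 (hypoxia and glycolysis). Immediate early and stress also missed the threshold without pancreatic cancer replicate 11 (adjusted p = 0.0864) or healthy control replicate 2 (0.0574), 8 (0.0614) or 11 (0.0546), and its median came nearest to 0, at -0.15, without healthy control replicate 5. Ribosomal protein also missed it without healthy control replicate 4 (adjusted p = 0.108).

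The group did not account for the array sets, since the smallest cell of group by set held 5 arrays. An uneven scale did not account for them either, since 3852 probe sets still differed after quantile normalization, against 4051 before it. Hybridization, staining or scanning that differed between the sets was neither shown nor excluded: the other hybridization controls had a median log2 difference of -1.55, low minus high, but they are added in 1 mix with BioB, which defines the sets. The controls did not split every array alike. Healthy control replicate 10, low by BioB (105.2), had 17756.5 at the control cre. That exceeded the high-control pancreatic cancer replicates 10 (17310.9) and 12 (15984.7). The 3' minus 5' control signal also differed between the sets, by 1.04, but its 5' end lay near background in both sets, so the amount or quality of the RNA stays open as well. The labels give no batch, so no biological explanation was tested.

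At the preset correlation, lower neutrophil genes in cancer on high-control arrays did not rest on 1 array. The largest adjusted p on leaving out each array was 0.00919. The estimated correlation of the list there was 0.13, so this p cannot exclude that a few arrays carry the result. Genes that move together from array to array remained possible: with an estimated correlation p was 0.0477, which met the planned bound of an unadjusted p under 0.05 only narrowly, and the adjusted p was 0.398, so after that value was seen the explanation was kept as undecided. Less saliva RNA on the cancer arrays also remained possible, since 24 well measured squamous and ribosomal genes had a median log2 difference of -0.34 (95% interval -0.88 to 0.08). That interval comes from resampling the genes and does not measure the spread between samples. Among neutrophil genes, 9 of 11 well measured ones were lower, with a median of -1.66. At least as many lists passed on these arrays in 36 of 100 splits of the groups (highest other 4, real 1), so chance remained possible.

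For lower TPT1 in cancer on high-control arrays, a signal of 1 probe set could not be weighed against a fall of the transcript. The called probe set against 3 other TPT1 probe sets differed between the groups by -2.30 on the log2 scale. On the cancer arrays its median intensity was 12.9, near background, against 327.2, 546.2 and 433.3 at those 3. The called probe set was picked for its large difference, so the contrast cannot decide the question. The mean of those 3 probe sets differed by -2.44 (exact permutation p = 0.0746), so a fall of the transcript itself was neither shown nor excluded.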

How the results depend on the processing

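The array set block, the high-control and low-control settings and the estimated correlation with array weights were chosen after results were seen. All 4 probe sets called between the groups (1 higher, 3 lower) kept their calls with an offset of 1, quantile normalization, median centring, dim probe sets left out, array weights, the 3' minus 5' covariate, the array set block and without each array in turn. Dim here means a mean log2 value not above the median of all tested probe sets. CDKL3 and CD7 stayed in, with median intensities of 0 and 1 in cancer, so that setting did not remove all probe sets near background. With a variance trend and robust fit 3 were kept, with the exact Wilcoxon test 1, with low-control arrays only 1, and with an offset of 64, the replicate block or high-control arrays only 0. The called counts were 9 with 6 higher at an offset of 1; 0 with 0 higher and 0 lower at an offset of 64 (2438 at an unadjusted p under 0.05); 2 higher after quantile normalization; 8 with 5 higher without dim probe sets; 8 with 6 higher with trend and robust fit; 2 with 1 lower by Wilcoxon; 10 with 6 higher with the 3' minus 5' covariate; 3 higher with the array set block; 2 higher on high-control arrays; 2 with 2 higher and 0 lower on low-control arrays; and 0 with representative probe sets only. Without 1 array the count ranged from 4 to 7 (higher 1 to 4, lower 3 to 4), reaching 7 without pancreatic cancer replicate 2, healthy control replicate 1 or healthy control replicate 12.

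Samples share only a number across groups: 5 of 12 pairs correlated over 0.1, and 1 of 12 cancer arrays correlated best with its own number. Blocking on that number gave 0 calls, 0 higher and 0 lower (2509 at an unadjusted p under 0.05). Lists past the threshold were 1 with array weights (ribosomal protein, adjusted p = 0.00846, median 0.18), 1 on high-control arrays, 5 on low-control arrays, and 0 without each array in turn. With an estimated correlation the 3 settings that called lists called 0 (lowest adjusted p = 0.52 with array weights, 0.384 on high-control and 0.575 on low-control arrays). Published candidates called over the list alone were 8 with the mean of probe sets, 1 on low-control arrays, and 4 without each array in turn, when 0 were called over all probe sets. The 3' minus 5' group difference, 0.03, was -0.04 at an offset of 64, -0.16 with GAPDH alone, -0.45 on high-control arrays, 0.42 on low-control arrays, and -0.09 to 0.21 without 1 array.

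Of 4311 values of 114 named probe sets under the alternatives, 4234 kept direction and side of the threshold, 39 passed it only there, 15 lost it and 23 changed sign. Only 3 of the 114 were called in the main fit, so most kept their side by staying uncalled. The 114 leave out probe sets named only from the array sets or as non-representative. Among those, sign changes on low-control arrays included IFI27L1 (-0.86), UGGT1 (-0.56) and the called TPT1 probe set (0.67). Those on high-control arrays included S100A8 (-1.66), S100A9 (-1.67), SPRR3 (-0.53), CSF1R (0.13), NRL (0.07), DDX25 (0.07) and CENPF (0.01). On low-control arrays the sign changed for DMXL2 (0.13), representative TPT1 (1.19), ZG16B (-0.07), SRGN (0.33), TYROBP (0.09), FCN1 (-0.03), MRC1 (0.00), POU2AF1 (-0.02), CA1 (0.10), RPS14 (-0.25), CXCL8 (0.40), EGR1 (0.36), CPA1 (-0.11), SAT1 (1.0), TUBA1B (0.03), MYL11 (-0.07) and CKM (-0.07), on high-control arrays for representative TK2 (-0.76) and NOP53 (-0.02), with array weights for representative TPT1 (0.29), and without 1 array for DMXL2 (-0.20 to 0.06, positive without healthy control replicate 11), representative CDKL3 (-0.28 to 0.00, without healthy control replicate 5) and NOP53 (-0.01 to 0.04, negative without pancreatic cancer replicate 3). On low-control arrays SRGN had -0.34 and CXCL8 -0.18 without pancreatic cancer replicate 1. The settings with 1 array set hold fewer samples; for the others the cause was not tested. Signal near background limits all dim genes, with at most 7.31% of an array's values over 100.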

Other observations

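The tests in this part were chosen after the group comparison was seen. Single genes of the secretory and squamous layers differed between the array sets, though the squamous list did not (camera adjusted p = 0.914) and the secretory list passed only at the preset correlation (adjusted p = 0.213 when estimated). PIGR, the immunoglobulin receptor of secretory epithelium, had a median intensity of 124.7 on high-control and 24.3 on low-control arrays, and a cancer minus control log2 difference of 0.33 (SE 0.42, n = 12 and 12). SPRR3, at its representative probe set, had 1110 and 43.8, and a log2 difference between the groups of 0.76 (SE 0.98), which was -0.53 on high-control and 1.66 on low-control arrays. Without pancreatic cancer replicate 6 the high-control value was 0.31. CSF1R, the macrophage growth factor receptor, and CENPF, a kinetochore protein, were brighter on low-control arrays, with set differences of -1.75 and -1.58. CSF1R hardly varied on high-control arrays, at 8.98 ± 0.08 (SD, n = 7) in cancer and 8.84 ± 0.10 (SD, n = 6) in control samples. NRL and DDX25 differed in the same way, by -1.51 and -1.23. The monocyte macrophage and cell cycle lists did not pass between the sets (camera adjusted p = 0.754 and 0.326), so no signal of macrophages or dividing cells was shown.

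One hypothesis was that few calls hide a separation of the groups by several probe sets at once. With 10 probe sets picked inside each of 6 folds, an area under the ROC curve was taken on the few left-out arrays of each fold. Its mean over folds and 10 repeats was 0.996. Of 100 permutations of the group labels, each averaged over 3 repeats in place of 10, 0 gave an area as large (median 0.549, range 0.139 to 0.903). The separation thus carried over to arrays not used to pick the probe sets. Cancer against control and any unrecorded difference in collection or handling between the groups cannot be separated here, so the area says nothing on other saliva samples.

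Another was that chance splits of the 24 arrays give as many calls as the real groups. As many probe sets as the 4 called between the groups came in 1 of 100 splits, the real one itself, with 3 the highest other. That is the smallest share 100 splits can give, and the counts tested in this way were not adjusted for their number. Chance was thus made less likely but not excluded. With the array set as a block the real 6 came in 1 of 100 (highest other 1), and the 4 called on high-control arrays in 2 of 100 (highest other 6). The 2 called on low-control arrays came in 4 of 100 (highest other 3). The 5 lists on low-control arrays came in 10 of 100 (highest other 7), so chance remained possible for them. The count of 0 lists between the groups could not be tested in this way, since all 100 splits give at least 0 (highest other 3). The 4 published candidates called over the list alone came in 1 of 100 (highest other 1), which carries no weight because the list was chosen on these samples.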
